A study of Mus musculus with 6 samples.

How the data were processed

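RNA of whole liver was sequenced from 6 male C57BL/6J mice at 10 weeks of age, 3 KI and 3 WT animals, with 1 library per animal. Each library was assigned to its group by its title. The deposited values are FPKM per gene, computed by the authors with 1 column per library, per the file headers. The submitters' processing notes name CASAVA 1.7, Bowtie 0.12.2 and genome build mm8. The program that computed FPKM, the gene annotation and the use of strand are not given in the sources used here. Each of 52636 genes was listed by its Ensembl identifier, of which 52403 (99.6%) matched a symbol.

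The FPKM values held whole reads. Multiplied by the summed exon length of each gene in GENCODE M21 and by 1 factor per library, 92.3% to 92.7% of the values under 1000 reads fell within 0.02 of a whole number. For 24576 of 26877 genes above 0 (91.4%) the values came out whole in all 6 libraries, and 233 genes had no length. This fit points to an annotation of a later assembly than mm8, and all coordinates given here are those of GENCODE M21 on GRCm38. Recovered reads numbered 29764871 to 37984365 per library, and 3 reads on 1 kb of exon were worth 0.0743 to 0.0943 FPKM. The per-million denominators followed median-of-ratios size factors of these reads (ratio 0.987 to 0.996) and not the read totals, whose own ratio to these factors was 0.922 to 1.13, so the authors' values were already scaled between libraries. Such scaling assumes that most genes do not change. Depth figures cover counting error only.

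The planned count test did not apply because the values were FPKM, and the test planned for normalized values was used. Genes with a mean of at least 1 FPKM over the 6 libraries (10484 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with an intensity-dependent prior variance and no covariate. Benjamini-Hochberg adjusted p under 0.05 was the threshold, and every limma adjusted p given here is of this kind. Differences are KI minus WT on the log2(FPKM + 1) scale, which understates the change of genes with low FPKM. Where a gene was listed at 0 in each library of a group no fold is given. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.

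The tests, the alternatives not named as later, 36 gene lists and the rule for named genes were fixed before the data were examined. Named genes were Hnf1a, the 12 largest rises and 12 largest falls among called genes without overlap between groups, leaving out predicted and unnamed models, and the 4 members of each list with the smallest p. The 31 lists with at least 5 tested members were compared with all other genes by camera with a preset correlation of 0.01. Camera with a correlation estimated per list, and fry, which tests whether a list's genes move on balance one way, were run beside it, each with Benjamini-Hochberg adjustment over the lists. Rise and fall counts per list are also given with p adjusted over the list alone.

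The steps were tested on simulated data, with changes placed in the KI against WT comparison of 10405 genes. Of 100 genes changed 2-fold 47 were called, and of 100 changed 4-fold 84, with 11 unchanged genes called. Camera called the shifted list and 0 of 20 unshifted lists. Simulated genes varied independently, whereas the correlation estimated for the real cholesterol biosynthesis list was 0.61. The simulation therefore cannot show false list calls that arise where genes of a list vary together.

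Alternatives were a pseudocount of 0.1 or 5, no filter on low values, each library left out in turn, a block for animals with neighbouring numbers, and a fold threshold. Later additions were voom on recovered reads, rescaling to a common FPKM total or to recovered read totals, KI 16 and WT 19 as a batch or left out, and removal of per-library trends with GC content and length. For the named and sex-biased genes among others, the share of each gene's 50-base sequences that also occur in transcripts of other genes was counted in GENCODE M21, since the authors' treatment of reads shared between genes is not given in the sources used here.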

Results

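Livers of 10-week-old male C57BL/6J mice were profiled by RNA sequencing in 2 groups of 3 libraries each. KI mice carried a knock-in in which lysine 117 of HNF1α, a homeodomain transcription factor of liver, pancreas, kidney and gut, was replaced by glutamate (K117E). WT mice were the control. The comparison asks what this substitution, a human disease mutation placed in the mouse gene by CRISPR/Cas9, does to the transcripts of the liver. The libraries carry animal numbers, 16, 55 and 72 for KI and 19, 54 and 74 for WT. The labels do not settle whether the KI animals carried the change on one or both alleles. Values were the authors' FPKM, fragments per kilobase of exon scaled by 1 factor per library. The reads recovered from them numbered 29764871 to 37984365 per library, so that 3 reads on 1 kb of exon corresponded to 0.0743 to 0.0943 FPKM.

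No difference in expression of the edited gene itself was detected between the groups. Hnf1a (ENSMUSG00000029556) stood at 6.29 ± 2.30 FPKM in KI livers and 5.63 ± 1.07 FPKM in WT livers (mean ± SD, n = 3 each), a difference of 0.09 ± 0.26 (SE) on the log2(FPKM + 1) scale, within the spread between animals (limma, Benjamini-Hochberg adjusted p = 0.938). In mouse assembly GRCm38, with GENCODE M21 annotation, the gene spans 114948980 to 114971094 of chromosome 5 on the minus strand. Codon 117 lies at 114960191 to 114960193, in coding exon 2 of 10 (114960016 to 114960215), within a reading frame of 628 residues, and encodes K in the reference. Because a change of 1 residue need not alter the amount of mRNA, this level is a measurement and does not check the labels.

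**Figure D1:**
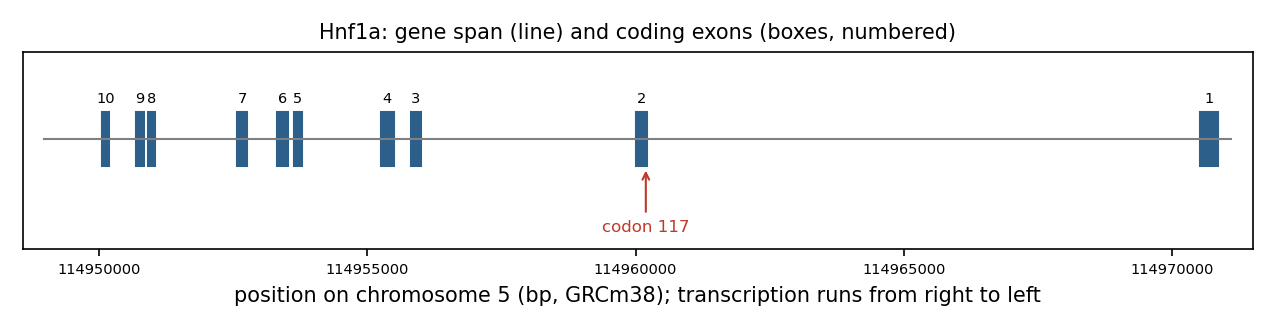
Map of the mouse Hnf1a gene on chromosome 5 (x axis, position in bp, GRCm38). The line is the gene span, boxes are the 10 coding exons of the transcript with the longest reading frame, and the arrow marks codon 117 in coding exon 2.

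Genotype was the main axis of variation. Of 10484 genes tested, 192 were higher and 297 lower in KI than in WT livers at an adjusted p under 0.05 (limma with Benjamini-Hochberg adjustment), and in each of these 489 genes the 3 KI and 3 WT values did not overlap. Across every gene tested, 20.9% had non-overlapping groups, where chance gives 10%. At least a doubling on the log2(FPKM + 1) scale was reached by 124 of the higher genes and at least a halving by 233 of the lower ones. This scale understates the change of genes with low FPKM. The first principal component held 59.5% of the variance and separated the genotypes, while the second held 26.2% and ran from KI 16 and WT 19 at one end to KI 55 and WT 74 at the other. Mitochondrial genes held 16.6% of the FPKM in KI 16 and in WT 19, 32.8% in KI 55 and 26.6% in WT 74, and 23.9% in KI 72 and 19.5% in WT 54. The counts fell with single animals left out, which also leaves fewer samples. Without WT 54, KI 72, WT 74, KI 55 or KI 16 the higher genes numbered 66, 76, 100, 108 or 121. Without KI 72, WT 54 or KI 55 the lower genes numbered 167, 172 or 188. A call lost in such a fit does not by itself show that 1 animal carried the difference. With FPKM rescaled to 1 common total, which raised the median log2 difference by 0.13, the balance of higher to lower genes moved from 39.3% higher to 50.4% higher, and with rescaling to recovered read totals, which raised it by 0.07, to 50.2%.

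**Figure D2:**
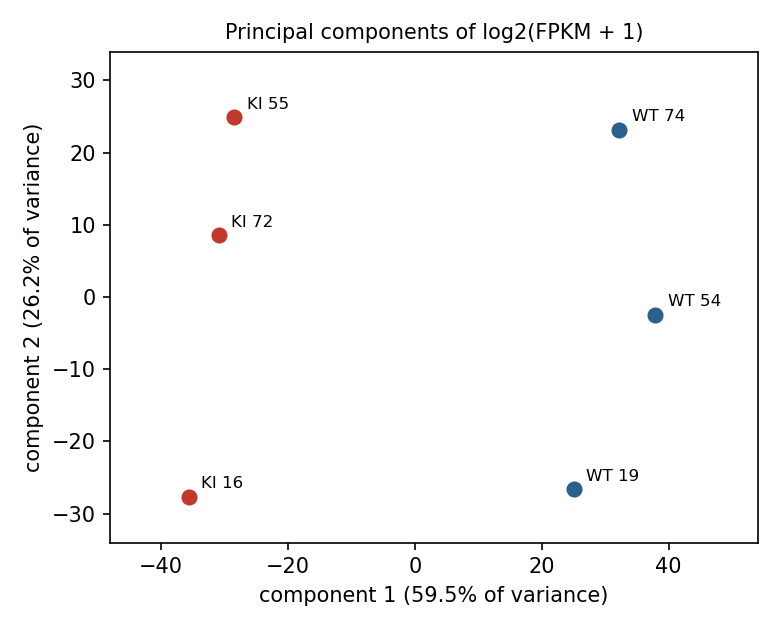
Principal components of log2(FPKM + 1) for the 6 libraries, with component 1 on the x axis and component 2 on the y axis (arbitrary units) and 1 point per library. KI libraries lie at −35.6 to −28.5 and WT libraries at 25.0 to 37.9 on component 1, while KI 16 and WT 19 lie at −27.6 and −26.6 and KI 55 and WT 74 at 24.9 and 23.2 on component 2.

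Some of the most abundant liver transcripts were nearly lost. Fabp1, the liver fatty acid-binding protein, fell from 9311 ± 1101 FPKM in WT to 90.6 ± 74.1 FPKM in KI livers (log2 −7.05 ± 0.62 SE, limma adjusted p = 0.00146). The arachidonic acid epoxygenase Cyp2j5 fell from 176 ± 56.1 to 0.588 ± 0.489 FPKM, and C8a, which encodes the alpha chain of complement component 8, from 187 ± 38.8 to 0.221 ± 0.123 FPKM. Most of the 12 largest falls were in genes for major urinary proteins (Mup), pheromone carriers made in male liver and excreted in urine. Mup12 fell by 10.97 and Mup7 by 10.42 on the log2 scale, and of 29 Mup genes and pseudogenes tested 20 fell and 0 rose, with a median of −4.34. Single members of this family are uncertain, since 90.2% of the 50-base sequences of Mup7 and 85.4% of those of Mup12 also occur in transcripts of other genes. Serpina1e, a gene for an alpha-1-antitrypsin, fell from 4608 ± 2958 to 8.36 ± 3.49 FPKM, with 35.6% of its sequence shared, and the pseudogene Serpina4-ps1 from 126 ± 68.2 to 0.112 ± 0.110 FPKM. Among the 12 largest rises, the flavin monooxygenase Fmo3 went from 0.123 ± 0.0838 to 142 ± 42.3 FPKM (log2 6.96 ± 0.21 SE, limma adjusted p = 2.66e-05). The cytochrome P450 gene Cyp2b9 went from 0.893 ± 1.08 to 150.5 ± 19.2 FPKM, the sulfotransferase gene Sult1e1 from 0.362 ± 0.137 to 36.4 ± 14.1 FPKM, and the surface protein gene Ly6d from 1.76 ± 0.887 to 88.3 ± 24.4 FPKM. Sult2a2 was listed at 0 in each WT library and stood at 53.4 ± 29.3 FPKM in KI livers, although 62.1% of its 50-base sequences are shared with other genes. Hamp2, a gene of the hepcidin family with 15.5% of its sequence shared, rose by 3.66 (adjusted p = 0.0297), a call lost without KI 16, KI 55 or KI 72 (limma adjusted p = 0.0764, 0.0995 and 0.0867).

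**Figure D3:**
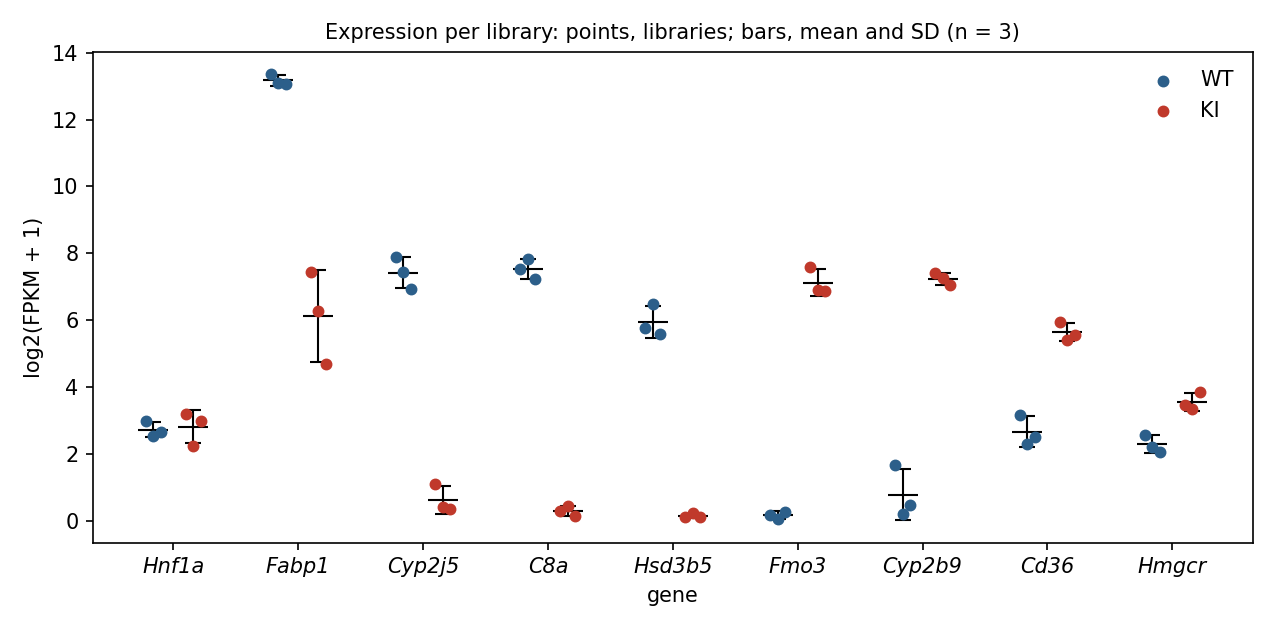
Expression of 9 genes per library on the log2(FPKM + 1) scale (y axis), with blue points for WT and red for KI libraries and black bars for the mean ± SD (n = 3). The groups overlap for Hnf1a and are apart for the other 8 genes, which fell (Fabp1, Cyp2j5, C8a, Hsd3b5) or rose (Fmo3, Cyp2b9, Cd36, Hmgcr) in KI livers.

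Of the gene lists fixed beforehand, those of genes that differ between the sexes in mouse liver had the medians farthest from 0. Of 17 male-biased genes tested 15 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of −3.51. Hsd3b5, a steroid dehydrogenase gene, fell from 62.8 ± 22.4 to 0.103 ± 0.0517 FPKM, the glucuronosyltransferase gene Ugt2b1 from 154 ± 65.5 to 0.581 ± 0.351 FPKM, and Keg1 from 17.7 ± 4.24 to 0.525 ± 0.166 FPKM; 21.2% of the 50-base sequences of Hsd3b5 are shared with other genes. Of 14 female-biased genes tested 10 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 2.78. They included Fmo3 and Cyp2b9, as well as Cyp2b13, which went from 0.0159 ± 0.0154 to 46.2 ± 14.5 FPKM, and Sult2a1, which went from 0.0669 ± 0.0599 to 11.6 ± 1.10 FPKM. Of Cyp2b13 and Sult2a1, 27.3% and 33.2% of the 50-base sequences are shared with other genes. Both lists stood apart from other genes by camera with a preset correlation (adjusted p = 4.08e-28 and 1.75e-20). That call was not kept with correlations estimated from the data (adjusted p = 0.283 and 0.175 with an estimated correlation), while fry, which tests whether a list's own genes move one way, gave 0.00340 and 0.000936. The growth hormone and IGF axis, 11 genes, had 1 fall and 0 rises (3 and 2 adjusted over the list alone) and was called by fry (adjusted p = 0.00545) but not by camera (0.0813). Its fall was in Igfals, which encodes the binding partner of circulating IGF complexes and went from 47.1 ± 5.83 to 15.7 ± 0.814 FPKM. Igf1 differed by −0.64 (limma adjusted p = 0.159). Igfbp1 stood at 347 ± 62.1 FPKM in KI and 59.8 ± 62.7 FPKM in WT livers (limma adjusted p = 0.0508). By limma adjusted p, Igfbp1 passed without WT 19 (0.000702) or with KI 16 and WT 19 as a batch (0.00987). It did not pass with any other single library left out (limma adjusted p = 0.126 to 0.196). Without WT 19 this list had 2 falls and 1 rise.

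Among 29 genes listed beforehand as HNF1A targets in liver, 8 fell and 0 rose (13 and 2 adjusted over the list alone), with a median of −0.61 and differences from −7.05 to 0.69. Besides Fabp1 and Cyp2j5, Apom, the gene for an HDL apolipoprotein, fell from 56.2 ± 25.7 to 0.901 ± 0.432 FPKM and Dpp4, a membrane peptidase gene, from 12.1 ± 1.55 to 2.06 ± 0.450 FPKM. Camera placed the list below other genes (adjusted p = 1.00e-08, but adjusted p = 0.301 with an estimated correlation), and fry gave 0.0217. Of 21 liver-enriched transcription factors 1 fell and 0 rose (1 and 0 adjusted over the list alone), with a median of −0.18 and camera adjusted p = 0.00530 (adjusted p = 0.301 with an estimated correlation). The fall was in Nr1h4, the bile acid receptor FXR, from 81.4 ± 21.0 to 35.5 ± 6.99 FPKM (limma adjusted p = 0.0479). It passed without WT 19 but not without KI 16, WT 54, KI 55, KI 72 or WT 74, where the adjusted p reached 0.187. Foxa2, Tbx3 and Ppara differed by −0.74, −1.08 and −0.45 (limma adjusted p = 0.136, 0.138 and 0.257). Foxa2 passed with a block for neighbouring animal numbers (0.0343) and Tbx3 with KI 16 and WT 19 left out (0.0393). Neither Foxa2 nor Tbx3 passed with any single library left out (limma adjusted p = 0.173 to 0.303 and 0.0789 to 0.431).

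Bile acid genes changed in both directions. Slco1a1 and Cyp7b1, among the falls below, also belong to the male-biased list and are counted there too. Of 13 transporters of bile acids and organic anions 2 rose and 2 fell (3 and 3 adjusted over the list alone). Slc51b, a subunit of the basolateral bile acid exporter, rose from 0.214 ± 0.123 to 5.92 ± 0.818 FPKM and Slco1a4 from 8.03 ± 3.44 to 57.1 ± 7.98 FPKM. Slco1a1 fell from 52.4 ± 17.3 to 4.04 ± 1.22 FPKM and Slc22a7 fell by 2.58 on the log2 scale. The call of Slc22a7 was lost without KI 72 (limma adjusted p = 0.0521), which left 1 fall in this list. Among 13 genes of bile acid synthesis 1 rose and 2 fell (1 and 2 adjusted over the list alone). Akr1d1, a steroid reductase gene, rose from 40.7 ± 8.71 to 123 ± 17.8 FPKM, and Cyp7b1 and Akr1c6 fell by 2.93 and 1.85 on the log2 scale. These 3 calls were not kept without KI 72 (limma adjusted p = 0.0520, 0.0791 and 0.188). Cyp7b1 and Akr1c6 also did not pass without WT 19 (0.0593 and 0.113) or KI 55 (0.0792 and 0.133), nor Cyp7b1 without KI 16 (0.0575) and Akr1c6 without WT 54 (0.193). The falls numbered 1 without KI 16 or WT 54 and 0 without WT 19, KI 55 or KI 72. Cyp7a1, the rate-limiting enzyme of the classic pathway, stood at 83.5 ± 17.7 FPKM in KI and 24.5 ± 19.5 FPKM in WT livers, a difference that did not pass (limma adjusted p = 0.228) but did with KI 16 and WT 19 both left out (0.0464) or treated as a batch (0.0407). Cyp7a1 did not pass with any single library left out (limma adjusted p = 0.077 to 0.527). Neither list was called by camera (adjusted p = 0.997 and 0.840) or fry (0.424 and 0.988), and for the transporters the median of −0.07 and the direction of the camera test differed in sign. The direction of the camera test also turned for the transporters without KI 16 or WT 74 (0.732 and 0.684) and for bile acid synthesis without WT 19, WT 54 or KI 55 (0.517, 0.948 and 0.810).

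Genes of fat uptake and synthesis rose in part. Of 15 lipid droplet genes 3 rose and 0 fell (4 and 1 adjusted over the list alone). The fatty acid transporter gene Cd36 went from 5.56 ± 2.16 to 49.3 ± 9.83 FPKM, the acyltransferase gene Mogat1 from 0.364 ± 0.0503 to 2.68 ± 0.559 FPKM, and the nuclear receptor gene Pparg from 2.28 ± 0.333 to 6.21 ± 0.783 FPKM. G0s2 differed by −1.20 (limma adjusted p = 0.0893, and 0.0373 with KI 16 and WT 19 as a batch). G0s2 did not pass with any single library left out (limma adjusted p = 0.0764 to 0.213). In de novo lipogenesis 4 of 18 genes rose and 0 fell (6 and 0 adjusted over the list alone), with a median of 0.70. The fatty acid synthase gene Fasn went from 23.9 ± 1.78 to 51.2 ± 1.31 FPKM and the elongase gene Elovl6 from 10.0 ± 1.57 to 41.6 ± 14.6 FPKM, and Elovl5 and Acaca rose by 1.73 and 0.71 on the log2 scale, with 52.6% of the 50-base sequences of Acaca shared with other genes. In cholesterol biosynthesis 4 of 22 genes rose and 0 fell (5 and 0 adjusted over the list alone), with a median of 0.55. These were Hmgcr, the rate-limiting reductase, from 3.91 ± 0.938 to 10.9 ± 2.28 FPKM, Hmgcs1, the synthase before it, from 47.9 ± 19.2 to 135 ± 23.8 FPKM, Lss and Sc5d. Camera called the lists (adjusted p = 0.00143 for lipid droplets, 3.20e-06 for lipogenesis and 2.04e-05 for cholesterol), though not with estimated correlations (adjusted p = 0.301, 0.301 and 0.410 with an estimated correlation). By adjusted p, fry called lipogenesis (0.0258) but not lipid droplets (0.0647) or cholesterol (0.168). The cholesterol rises numbered 1, 2, 1, 1, 0 and 1 without KI 16, WT 19, WT 54, KI 55, KI 72 and WT 74, and the lipogenesis rises numbered 2 without each library except WT 19, where they numbered 3. Per-library medians of the cholesterol list, taken relative to each gene's mean over the 6 libraries, overlapped between the groups. KI 55 lay at −0.17, below WT 19 and WT 54 at −0.09 and −0.02. KI 16, KI 72 and WT 74 lay at 0.46, 0.47 and −0.75.

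Fatty acid oxidation and PPARA targets, 24 genes, had 2 rises and 3 falls (5 and 3 adjusted over the list alone), with no call by camera (adjusted p = 0.374) or fry (0.661). Cyp4a14, an omega-hydroxylase gene, rose from 175 ± 37.4 to 556 ± 101 FPKM, a call lost without KI 72 (limma adjusted p = 0.0553), and Acot2 from 3.29 ± 0.584 to 8.44 ± 0.485 FPKM, with 27.7% of its 50-base sequences shared, while the pantetheinase gene Vnn1 fell from 13.2 ± 0.131 to 3.65 ± 0.771 FPKM. The falls numbered 1 without KI 16 or KI 72, and the rises 1 without KI 72. Of 24 genes of lipoproteins and lipid export 2 fell and 0 rose (2 and 1 adjusted over the list alone). These were Apom and Apoa1, the main HDL apolipoprotein, at 7694 ± 420 FPKM in KI and 13254 ± 1675 FPKM in WT livers (limma adjusted p = 0.0474), the latter not called with any 1 library left out (0.0969 to 0.225). This list was not called by camera (adjusted p = 0.801) or fry (0.795), and its median of 0.04 and mean of −0.07 differed in sign. The falls numbered 1 without each library, the rises 1 without WT 19, and the camera test turned downward without KI 72 (0.992).

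In gluconeogenesis 2 of 11 genes rose and 0 fell (4 and 0 adjusted over the list alone), with a median of 0.62. The coactivator gene Ppargc1a went from 0.952 ± 0.294 to 3.79 ± 0.0907 FPKM and G6pc, the glucose-6-phosphatase gene, from 117 ± 25.8 to 302 ± 46.8 FPKM. The call of G6pc was lost without KI 16, WT 54, KI 55 or KI 72 (limma adjusted p = 0.0502 to 0.0760). By limma, 0 of 15 genes of glycolysis and fructolysis passed (5 at an unadjusted p under 0.05, 0 by voom on recovered reads, and 3 rises and 0 falls adjusted over the list alone), with Aldob at 3579 ± 111 FPKM in KI and 2196 ± 364 FPKM in WT livers (limma adjusted p = 0.0811, and 0.0409 with KI 16 and WT 19 as a batch). Aldob did not pass with any single library left out (limma adjusted p = 0.0586 to 0.318). In amino acid catabolism and the urea cycle 1 of 26 genes rose and 0 fell (2 and 0 adjusted over the list alone), namely the methionine adenosyltransferase gene Mat1a, from 805 ± 111 to 1633 ± 173 FPKM; without KI 16, WT 54, KI 55, KI 72 or WT 74 this call was lost (limma adjusted p = 0.0538 to 0.119) and 0 genes of the list rose, whereas 3 rose without WT 19. Camera called these lists upward (adjusted p = 0.000107, 0.00611 and 0.000965), with adjusted p = 0.340, 0.301 and 0.478 with an estimated correlation, and fry called none (0.0688, 0.0688 and 0.216). Per-library medians of the amino acid list, relative to each gene's mean over the 6 libraries, overlapped between the groups. KI 55 lay at −0.04, below WT 19 at 0.17, while KI 16 and KI 72 lay at 0.39 and 0.25. The 27 genes of oxidative phosphorylation differed by 0.16 to 0.63 with a median of 0.39, and 0 passed by limma (0 adjusted over the list alone, 6 at an unadjusted p under 0.05, and 0 by voom on recovered reads). Camera called that list (adjusted p = 1.03e-07, but adjusted p = 0.317 with an estimated correlation) and fry did not (0.0856).

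Drug-metabolizing and antioxidant genes rose in part. Of 17 targets of CAR, PXR and AHR 4 rose and 0 fell (6 and 1 adjusted over the list alone), with a median of 0.50. Cyp2b10 went from 1.97 ± 2.24 to 50.5 ± 26.7 FPKM, Cyp2c55 from 2.96 ± 1.26 to 32.1 ± 21.0 FPKM, Cyp2a5 from 231 ± 37.5 to 689 ± 176 FPKM and Cyp2c37 rose by 1.32 on the log2 scale. None of these 4 calls was kept without WT 54 (limma adjusted p = 0.0511, 0.0959, 0.0578 and 0.115), while 1 was kept without KI 72 and 2 without WT 74. Of the 50-base sequences of Cyp2a5 and Cyp2c37, 40.8% and 30.1% are shared with other genes. Cyp2a5 also did not pass without KI 55 (0.0507), nor Cyp2c37 without KI 16 or KI 55 (0.0617 and 0.0576), by limma adjusted p. Of 13 NRF2 targets 5 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.90. They included Nqo1, a quinone reductase gene, from 3.43 ± 0.845 to 10.1 ± 0.0937 FPKM, and the glutathione transferase gene Gsta2, from 14.7 ± 3.59 to 104 ± 23.8 FPKM, of whose sequence 64.2% is shared. Gsta1, also among these rises (by 1.32 on the log2 scale), has 89.7% of its 50-base sequences shared with other genes. The rises numbered 3 without WT 19, WT 54, KI 55 or WT 74 and 2 without KI 72. Camera called both lists (adjusted p = 2.04e-05 and 2.69e-07), with adjusted p = 0.301 for each with an estimated correlation, and fry called NRF2 targets (0.0245) but not the other list (0.0699).

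Transcripts of plasma proteins of defence and clotting fell in part. In complement 5 of 16 genes fell and 0 rose (9 and 0 adjusted over the list alone), with a median of −0.57. Besides C8a, C6 fell from 58.2 ± 4.68 to 4.35 ± 0.0984 FPKM, Hc, the gene for C5, from 116 ± 21.8 to 15.5 ± 4.51 FPKM, and Mbl1, a mannose-binding lectin gene, from 168 ± 38.7 to 56.1 ± 5.77 FPKM. Without KI 72 the call of Mbl1 was lost (limma adjusted p = 0.0503) and 3 genes of the list fell. Of 21 coagulation factors 2 fell and 0 rose (5 and 0 adjusted over the list alone), with a median of −0.42. Cpb2, which encodes a carboxypeptidase that slows clot breakdown, fell from 184 ± 61.6 to 4.77 ± 0.983 FPKM and F11 from 55.9 ± 10.9 to 21.0 ± 3.64 FPKM, the latter not passing without WT 54, KI 55 or KI 72 (limma adjusted p = 0.0719, 0.0507 and 0.0667). Plg, the plasminogen gene, differed by −1.17 (limma adjusted p = 0.0695, and 0.0358 without KI 16 or 0.0109 with KI 16 and WT 19 as a batch). Plg did not pass with any other single library left out (limma adjusted p = 0.0663 to 0.275). In the acute phase list 5 of 21 genes fell and 1 rose (9 and 1 adjusted over the list alone), with a median of −0.77. Apcs, the serum amyloid P gene, fell from 160 ± 113 to 7.86 ± 3.64 FPKM, and Socs3, a brake on cytokine signalling, from 12.7 ± 4.19 to 3.22 ± 0.626 FPKM, whereas Orm3 rose from 7.85 ± 2.37 to 48.0 ± 13.4 FPKM. The number of acute phase falls was 3, 2, 2, 2 and 8 without KI 16, WT 54, KI 55, KI 72 and WT 74. All 3 lists were called downward by camera (adjusted p = 5.19e-11, 0.000324 and 2.97e-07, against adjusted p = 0.301, 0.447 and 0.301 with an estimated correlation). By adjusted p, fry called complement (0.00390) but neither coagulation (0.119) nor acute phase (0.0699). Per-library medians of the coagulation list, relative to each gene's mean over the 6 libraries, overlapped between the groups. KI 16 lay at 0.04, above WT 74 at −0.18, while KI 55 and KI 72 lay at −0.24 and −0.22.

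**Figure D4:**
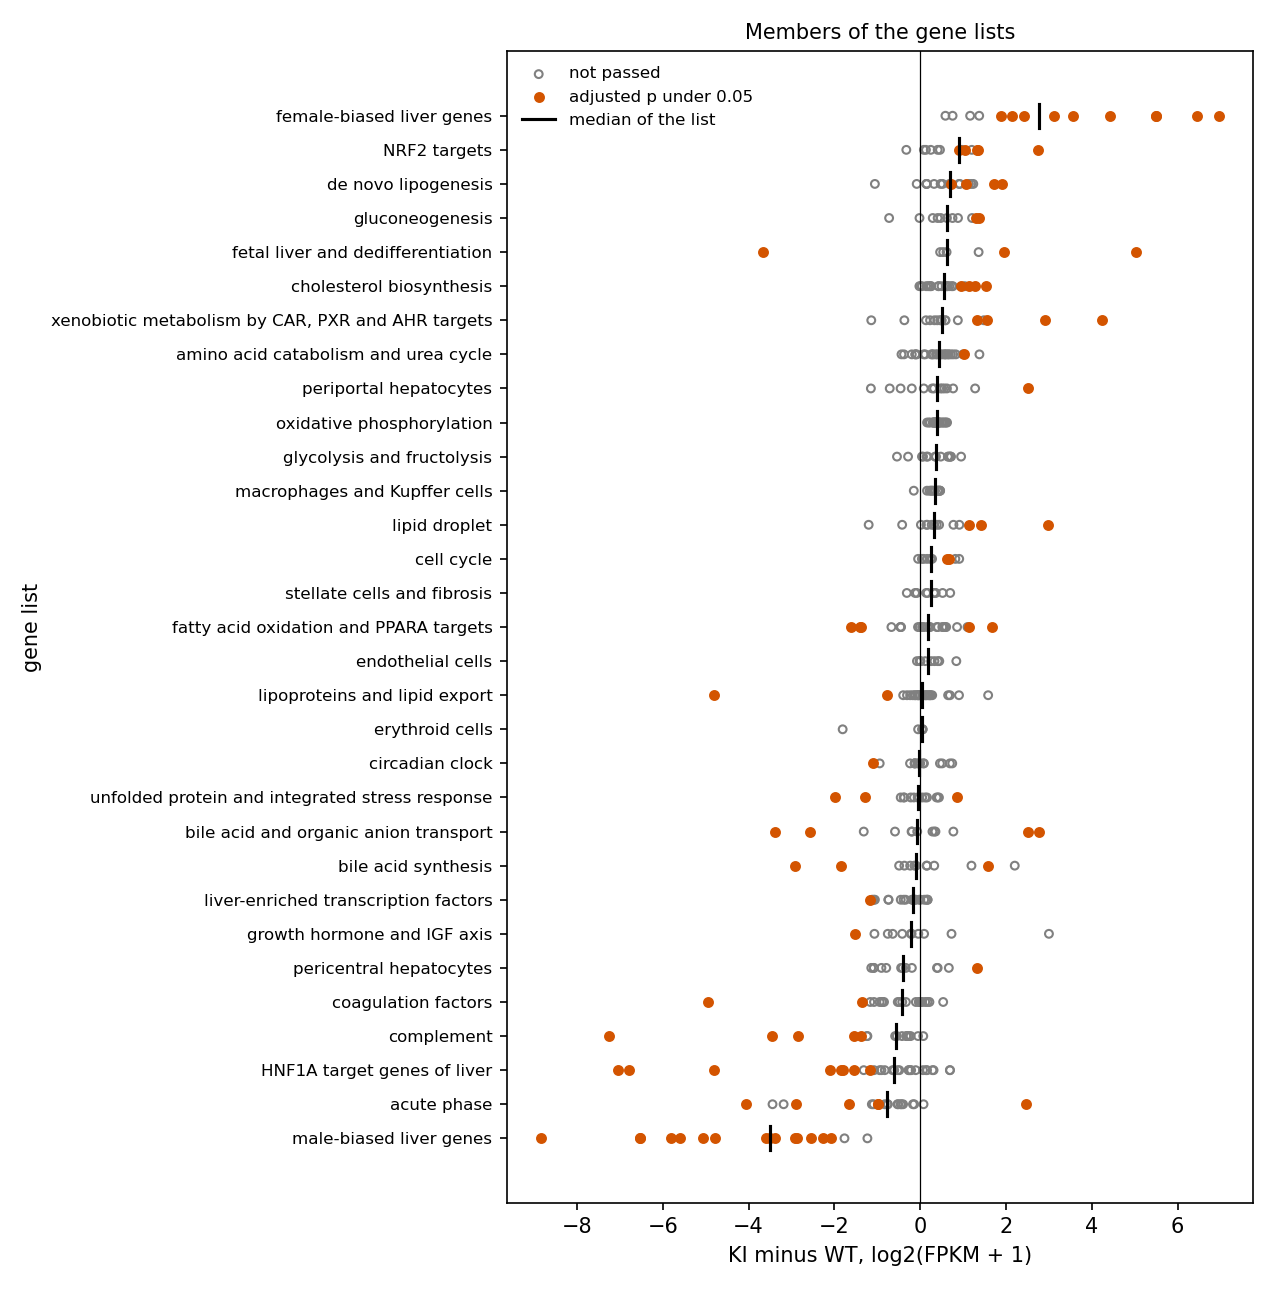
KI minus WT difference on the log2(FPKM + 1) scale (x axis) for every tested member of the 31 gene lists with at least 5 tested members (y axis), with filled points for genes at adjusted p under 0.05, open points for the rest and a bar at each list's median. Male-biased genes have a median of −3.51 and female-biased genes of 2.78, and the other medians lie between −0.77 and 0.90.

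The lists of dedifferentiation, growth, stress and the clock held 1 to 3 calls each. Of 7 fetal liver and dedifferentiation genes tested 2 rose and 1 fell (5 and 1 adjusted over the list alone). Ly6d rose, as did Scd2, a desaturase gene, from 0.457 ± 0.0768 to 5.11 ± 2.84 FPKM, and the trefoil factor gene Tff3 fell from 28.3 ± 3.75 to 1.37 ± 0.656 FPKM. Scd2 did not pass without WT 54, KI 72 or WT 74 (limma adjusted p = 0.0754, 0.0740 and 0.0598). Of 10 cell cycle genes tested Ccnb2 and Mcm6 rose and 0 fell (3 and 0 adjusted over the list alone), by 0.63 and 0.68 and at levels of 1.88 ± 0.302 and 1.54 ± 0.391 FPKM, respectively, in KI livers. Neither call was kept with any 1 library left out. Ube2c, of the same list, did not pass (limma adjusted p = 0.0512) but did without KI 72 (0.0307) or with KI 16 and WT 19 as a batch (0.0319). With any other single library left out Ube2c did not pass (limma adjusted p = 0.0749 to 0.203). Camera called both lists (adjusted p = 0.00189 and 0.00240), with adjusted p = 0.283 and 0.390 with an estimated correlation, and fry called the first (0.00340) but not the second (0.119). Of 16 genes of the unfolded protein and integrated stress response 1 rose (Asns, by 0.85) and 2 fell (Sdf2l1 by 1.99 and Xbp1 by 1.29), with the same counts adjusted over the list alone. None of these 3 calls was kept without WT 54, KI 55 or KI 72, with limma adjusted p up to 0.0838 for Asns, 0.0960 for Sdf2l1 and 0.195 for Xbp1. Asns also did not pass without WT 74 (0.0556), nor Sdf2l1 and Xbp1 without WT 19 (0.0538 and 0.115), where 2 genes of the list rose. Of 15 clock genes Nr1d1 fell by 1.09 and 0 rose (1 and 0 adjusted over the list alone), a call lost without WT 54, KI 55 or KI 72 (limma adjusted p = 0.0800, 0.0612 and 0.0791). Neither of these last lists was called by camera (adjusted p = 0.476 and 0.689) or fry (0.795 and 0.592), and the direction of the camera test turned for the first without WT 19 (0.689) and for the second without KI 16 or WT 74 (0.361 and 0.790).

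Neither list of hepatocyte zones was called as a whole by the main test, though other settings called each. Of 13 pericentral genes 1 rose and 0 fell (2 and 5 adjusted over the list alone), the riser being Cyp2c37, with Cyp2e1 and Cyp1a2 at −0.90 and −1.14 (limma adjusted p = 0.0966 and 0.0981, and 0.0277 and 0.0518 with KI 16 and WT 19 as a batch). Neither Cyp2e1 nor Cyp1a2 passed with any single library left out (limma adjusted p = 0.0584 to 0.336 and 0.0631 to 0.344). Cyp2c37 passed without WT 19 but not without KI 16, WT 54, KI 55, KI 72 or WT 74, where the limma adjusted p reached 0.115. Of 14 periportal genes Etnppl rose, from 13.6 ± 5.95 to 80.5 ± 24.2 FPKM, and 0 fell (2 and 1 adjusted over the list alone). Periportal rises numbered 2 without WT 19 and falls 1 without KI 16. Camera gave adjusted p = 0.0782 and 0.0993 and fry 0.381 and 0.424. Camera called the pericentral list downward without KI 72 or WT 74 (adjusted p = 0.0476 and 0.0335) and the periportal list upward without WT 19 (adjusted p = 0.00407). It also called the pericentral list with FPKM rescaled to 1 common total or to read totals (adjusted p = 0.0415 and 0.0279). The periportal list was called with a block for neighbouring animal numbers (adjusted p = 0.0453) and with KI 16 and WT 19 as a batch or left out (0.0403 and 0.00870). With an estimated correlation, all 6 libraries gave adjusted p = 0.540 for the pericentral and 0.696 for the periportal list.

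Other cell types gave few calls. Their markers had 0 calls by limma among 13 genes of macrophages and Kupffer cells, 10 of stellate cells and fibrosis, 10 of endothelial cells, 2 of cholangiocytes, 2 of lymphocytes, 4 of neutrophils, 5 of erythroid cells and 3 of adipocytes. At an unadjusted p under 0.05, 3 of the macrophage, 1 of the stellate, 2 of the endothelial and 2 of the adipocyte genes were higher and 1 erythroid gene was lower, and voom on recovered reads called 0. Adjusted over the list alone these counts were also 0, except for 1 erythroid fall in Alas2, which differed by −1.81 (limma adjusted p = 0.0746 over all genes tested, 0.0189 without WT 74, and 0.0331 with KI 16 and WT 19 as a batch). Alas2 did not pass with any other single library left out (limma adjusted p = 0.084 to 0.27). Macrophage genes had a median of 0.35 and were called upward by camera (adjusted p = 0.000616, but adjusted p = 0.390 with an estimated correlation). Endothelial genes had a median of 0.18 (camera adjusted p = 0.0443, and adjusted p = 0.301 with an estimated correlation), a call lost without WT 19, WT 54 or KI 55 (camera adjusted p = 0.152, 0.0501 and 0.187). That call was also lost by voom on recovered reads, without KI 16 and WT 19, and without GC and length trends (camera adjusted p = 0.0758, 0.0590 and 0.0845). Stellate (adjusted p = 0.0813) and erythroid genes (0.476) were not called by camera, but the stellate list was called upward without KI 72 or WT 74 (adjusted p = 0.00744 and 0.0185) or by voom on recovered reads (0.0271), against adjusted p = 0.543 with an estimated correlation and all 6 libraries, and the erythroid test turned upward without KI 16 or WT 54 (0.933 and 0.863). By adjusted p, fry called none of the 4 (0.148 for macrophages, 0.0678 for endothelial, 0.416 for stellate and 0.661 for erythroid genes). Of 13 exocrine pancreas genes 1 was tested, the elastase gene Cela1, which fell from 27.8 ± 7.19 to 4.87 ± 0.803 FPKM (1 fall adjusted over the list alone). The other 12 lay under the limit of a mean of 1 FPKM.

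Of 31 lists tested, camera with the preset correlation called 20, 14 upward and 6 downward, camera with an estimated correlation called 0, and fry called 8, of which 7 were among the 20. Of the 31, 27 were called by fry's test for change in either direction.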

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

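Rescaling, voom on recovered reads, both treatments of KI 16 and WT 19, and the removal of GC and length trends were chosen after seeing the data; the other settings were planned. Of 83 called genes among the 147 named besides Hnf1a, 48 were called under every alternative in which they were tested and 0 changed sign. Voom on recovered reads could test 438 of all 489 called genes. Without KI 16 and WT 19 the calls of Hamp2, Cyp7b1, Slc22a7, Hmgcs1, Lss, Sc5d, Acaca, Cyp4a31, Apoa1, G6pc, Mat1a, Ccnb2, Mcm6, Xbp1 and Srxn1 were lost (adjusted p = 0.0517 to 0.173). With a common FPKM total those of Nr1h4, Akr1c6, Apoa1, Xbp1 and Nr1d1 were lost. With no low-value filter 25 named genes lost their call, and with 1 library left out 11 to 33 did. Genes higher and lower numbered 185 and 298 with a pseudocount of 0.1, 180 and 270 with 5, 173 and 268 by limma-voom on recovered reads (9183 genes), and 145 and 254 without KI 16 and WT 19. With no low-value filter 111 were higher and 218 lower, where 26877 genes were adjusted for. With KI 16 and WT 19 as a batch 333 and 477 were called; the cause was not tested. At least a doubling was reached by 124. Leaving out 1 library gave 66 to 149 higher and 167 to 257 lower genes, with fewer samples. Camera called 19 to 22 lists under these settings, 0 with estimated correlations, and fry called 8. The direction of uncalled camera tests also turned without KI 16 and WT 19 for bile acid synthesis, bile acid transport and the clock (adjusted p = 0.878, 0.996 and 0.499). For transport it turned too with a pseudocount of 0.1, both rescalings and the removal of GC and length trends (adjusted p = 0.637 to 0.937); the cause was not tested.

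Hnf1a ranged from −0.10 to 0.38 on the log2 scale with 1 library left out and was below 0 without KI 16 or WT 54. None of the 11 other named genes that changed sign was called. With 1 library left out they ranged from −0.33 to 0.13 for Spp1, −0.054 to 0.044 for Hnf1b, −0.083 to 0.82 for Ighm, −0.33 to 0.023 for Nkg7, −0.11 to 1.27 for S100a9, −0.20 to 0.61 for Retnlg, −0.45 to 0.11 for Csf3r, −0.12 to 0.32 for Hbb-bt, −0.15 to 0.31 for Hbb-bs, −0.33 to 0.33 for Hba-a1 and −0.24 to 0.10 for Cfd. A common FPKM total gave 0.061 for Spp1, 0.11 for Hba-a1 and 0.0091 for Cfd, and read totals 0.040 for Hba-a1. Without KI 16 and WT 19 values were −0.11 for Hnf1b, 0.064 for Nkg7, −0.21 for S100a9, −0.31 for Retnlg, −0.059 for Hbb-bt and 0.084 for Hba-a1, and without GC and length trends −0.00049 for Hnf1b and 0.0073 for Hba-a1; the cause was not tested.

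The labels pair no KI animal with a WT animal, since they share no number. A planned block for neighbouring numbers gave 250 higher and 394 lower genes. Deviations from the group means correlated across genes at 0.65 for 16 and 19, 0.03 for 54 and 55, and 0.25 for 72 and 74. They correlated at 0.61 for 55 and 74. Deviations within a group are not independent, so these correlations do not settle whether neighbouring numbers pair the animals. Not run, because the files hold FPKM: count models with other size factors, upper-quartile scaling or plain totals, a second count tool, voom on deposited counts, count filters and a comparison of units. With 3 libraries per group and their spread, 47 of 100 simulated 2-fold changes and 84 of 100 simulated 4-fold changes were called. Changes of these sizes, and smaller ones, can therefore be missed.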

Other observations

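The test of GC and length trends, that of long non-coding RNAs and the count of called genes around Hnf1a were set out before their results were seen, but the bound for calling the last excluded was made stricter afterwards; every other test here, and the choice of the genes outside the fixed lists, came after.

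Several single-step metabolic genes outside the lists were nearly lost from KI livers. Prodh2, which encodes hydroxyproline dehydrogenase, fell by 6.42 ± 0.15 (SE, n = 3 per group) on the log2 scale, and Hao1, the gene for glycolate oxidase, fell by 5.80 ± 0.30. Agxt and Grhpr, which act on the glyoxylate these pathways form, differed by 0.26 and −0.52 (limma, Benjamini-Hochberg adjusted p = 0.810 and 0.466). Car5a, a mitochondrial carbonic anhydrase gene, fell by 4.21 ± 0.25. Hsd11b1, whose product activates glucocorticoids, fell from 86.5 ± 29.0 to 5.42 ± 0.920 FPKM (mean ± SD, n = 3). Among receptors, Egfr fell from 60.2 ± 12.3 to 20.4 ± 1.63 FPKM, Lifr from 23.5 ± 4.93 to 5.90 ± 0.764 FPKM and Il1r1 from 26.4 ± 7.46 to 6.41 ± 0.664 FPKM, whereas Met, Insr, Il6ra and Il6st did not pass. Lpl, the lipoprotein lipase gene, rose from 2.93 ± 0.530 to 25.7 ± 6.69 FPKM, Ucp2 from 5.82 ± 0.848 to 15.4 ± 0.542 FPKM and Lgals1 from 35.3 ± 6.73 to 224 ± 66.3 FPKM. The 10 genes given here as falling or rising passed with any 1 library left out. They come from a larger set looked at after the values were seen, in which some other called genes lost their call. Without KI 72, for example, Ttr and Gpx4 did not pass (limma adjusted p = 0.0864 and 0.108).

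Male-biased genes fell and female-biased genes rose in KI livers. Female animals among the KI libraries are argued against by the Y-linked gene Ddx3y, at 9.21 FPKM or more in each KI library, and by Xist, at 0.0116 FPKM or less there; neither tests an exchange of labels between males. Reads shared between near-identical genes do not account for the whole shift, since the 7 male-biased and 7 female-biased members with under 5% shared 50-base sequence had medians of −3.38 (quartiles −3.55 and −2.50) and 1.88 (quartiles 1.27 and 2.29). Of these members 6 and 4 were called. All tested members had medians of −3.51 and 2.78, so a part of the female-biased shift from shared reads is not excluded. A loss of male-type liver expression through HNF1α may be one hypothesis; growth hormone secretion, which sets these genes, and steroid levels were not measured and stay open.

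KI 16 and WT 19 lay at one end of the second component and KI 55 and WT 74 at the other, so the libraries may form a gradient. Deviations from the group means correlated across genes at 0.653 and 0.612 for these pairs, and mitochondrial genes held 16.6% of the FPKM in each of the first pair and 32.8% and 26.6% in the second. KI 16 and WT 19 also differed from the other 4 libraries, with Malat1 at 31.1 and 57.2 FPKM against 119 to 161 and Neat1 at 3.53 and 4.83 FPKM against 13.4 to 26.9. Trends with GC content and length are argued against as the whole cause, since the second component still held 23.5% of the variance after their removal (26.2% before). Less nuclear or unspliced RNA may be a cause: 388 other long non-coding RNAs lay at a median of −0.31 against the other libraries of their group, below each of 10000 random lists matched on expression (lowest −0.06), though a difference in library preparation would give the same. These RNAs are not independent replicates, and random lists matched on expression alone cannot show how a class that varies together would spread. Another time of day cannot be told apart. Clock genes deviated together at r = 0.547 across 15 genes, which are not independent replicates. This passed a first bound of 0.5, replaced after it was seen because matched random lists had a median of 0.796 and all genes gave 0.653. Dbp set KI 16 apart, at 5.07 FPKM against 23.5 FPKM in WT 19 and 18.9 to 38.8 FPKM over all other libraries. Arntl did so too, at 2.3 FPKM against 0.57 FPKM in WT 19, though its mean lay under the limit of 1 FPKM. Per2 was lowest in both KI 16 and WT 19, at 1.58 and 2.49 FPKM. Per1 and Ciart were instead lowest in WT 54, at 3.07 and 3.13 FPKM. They stood at 5.49 and 3.67 FPKM in KI 16 and at 6.74 and 8.86 FPKM in WT 19. KI minus WT differences between KI 16 and WT 19 and within the other 4 libraries correlated at 0.829 across genes.

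RNAs antisense to Hnf1a fell while Hnf1a did not. Hnf1aos1 (chromosome 5, 114968784 to 114998042) went from 6.22 ± 2.43 to 0.457 ± 0.0240 FPKM and Hnf1aos2 (114968823 to 114971400) from 3.57 ± 0.610 to 0.435 ± 0.224 FPKM (n = 3, limma adjusted p = 0.00222 for each). Both are uncertain because 31.8% and 80.5% of their exon bases lie in Hnf1a exons and the use of strand is not given. Whether reads of Hnf1a were counted for them stays open, since their difference from Hnf1a is the pattern itself and does not test it. A wider change around the edited site cannot be told apart, since 3 of 83 genes within 5 Mb, leaving out Hnf1a and both antisense RNAs, were called, or 3.61% (95% exact binomial interval 0.752% to 10.2%), against 4.66% elsewhere (Fisher's exact test, two-sided, p = 1). Under the first bound, a share at or below that elsewhere, a wider change would have been excluded; it was replaced because the interval includes the share elsewhere. One of the 3, 1810017P11Rik (114975456 to 114976013), lies within the span of Hnf1aos1, shares 0% of its exon bases with exons of Hnf1aos1 or Hnf1a, and fell too, by 1.87 (limma adjusted p = 0.0212). Its call was lost without KI 16, WT 54, KI 55 or WT 74 (0.0609 to 0.0724). That HNF1α drives the antisense RNAs may be a hypothesis, with no binding data in hand.

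The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split called 489 genes and was 1 of 10 with as many, while the highest other split called 0 by limma. The splits of KI 16 and WT 19 with WT 54 or KI 72 gave 1889 and 2081 genes at an unadjusted p under 0.05 against 1573 for the real one. For gene lists by camera the real split called 20, again 1 of 10, and the highest other, KI 16 with WT 54 and WT 74, called 18. Each other split sets 2 animals of a genotype and 1 of the other against the rest, so it still holds part of the difference between KI and WT.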
